A study of Homo sapiens with 39 samples.

How the data were processed

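RNA from 13 HEK293T lines, wild type or edited at AFF3, was sequenced in 39 libraries, 3 per line. Per the labels' protocols, the lines were made with CRISPR-Cas9, each was grown in biological triplicate, and libraries were made from poly(A)-selected RNA with a stranded kit. Per the submitters' processing notes, the tools were bcl2fastq, STAR 2.7.10b, featureCounts and DESeq2 1.36.0 on hg38. The submitters' notes do not state a role for DESeq2, an annotation, a strand setting or a filter.

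The 2 deposited tables are identical in content, 1 value per gene and library, so 1 was used. The deposited values are log2 CPM of the reads in the table's own genes, with no composition factor and a prior of 2 reads scaled to library size, although the name of the table speaks of counts. This was read from the values: the smallest value, -3.5901, is the same in all 39 libraries, and 99.94% of the values gave a whole number of reads within 0.1 reads (100% up to 1000 reads). Log2 values rebuilt from the whole reads lay within 5e-06 of the deposited ones. Each gene was above 1 CPM in at least 3 libraries, so silent genes were filtered out before deposit and are not analysed here. Recovered reads came to 17851969 to 31904826 per library. A count of 0 over a line allows up to 0.037 to 0.046 CPM (3 reads). Intervals and floors cover counting error only, since PCR copies were not told apart. No library was identical to another, and the chi-square per degree of freedom between libraries of a line was 2.386 to 33.87. The 2 highest values were those of library Wt4C against Wt4A (25.01) and Wt4B (33.87), and the next was 14.55.

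Of the gene identifiers, 14372 matched a symbol and 31 did not, and 14207 genes had a position in GRCh38.p14, the assembly of the gene table used for names and positions. Genes whose reads can be split with near-identical copies, overlapping genes and antisense genes are uncertain, because the counting by strand is not stated.

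The genotype comparisons, gene lists, filter, test threshold and rule for named genes were written before the data were examined. The plan was an edgeR quasi-likelihood test on reads summed per line, while the deposited values are log2 CPM and not counts. A test on the log2 scale was used instead, and the recovered reads were tested with voom as an alternative. The planned edgeR test was not run on the recovered reads. The log2 values were reduced by the log2 of each library's own TMM factor (0.934 to 1.067), averaged over the 3 libraries of a line and tested with limma 3.58.1 in R 4.3.3. The fit had 1 mean per genotype over all 13 lines, with moderated variances that follow expression (trend) and are robust to outlying genes. Adjusted p values are Benjamini-Hochberg values over the genes of a comparison, and a call is an adjusted p under 0.05. Genes with a CPM of at least 0.5 in at least 2 lines were tested, 14347 in all, and 56 were left out. The comparisons were the 4 mutant genotypes against wild type and the 3 pairs among DN/DN, LoF/LoF and DN/LoF. The LoF/+ genotype has 1 line, whose spread is taken from the other genotypes.

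The 33 gene lists were tested with camera at its preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Members were also adjusted over the list alone. Named genes are AFF3 in every line and its paralogs AFF1, AFF2 and AFF4. To these come, for the comparisons against wild type and for DN/DN against LoF/LoF, up to 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM in the higher group and no overlap between the groups. Where no gene passed, the 5 genes with the smallest p in each direction are given as values. The other comparisons name up to 5 per direction. Genes with clone or accession names only and annotated pseudogenes were not named, and within a list up to 4 members with the smallest p were. Some genes that these rules pick are not reported here. The correlation of effects was set against 1000 simulated draws of unchanged groups that share the wild-type lines. Ratios with 1 to 3 reads carry a 95% exact binomial interval of the pooled reads.

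The steps were tested on simulated data drawn from the real means and library sizes. For LoF/LoF against wild type, 64% and 50% of genes changed by 1 and -1 on the log2 scale were called, and 94% and 100% of those changed by 3 and -3, with 50 genes at each size among 14348 tested and 5 calls among unchanged genes. For DN/DN against wild type the shares were 30% and 32%, and 92% and 90%, among 14357 genes with 5 calls among unchanged ones. With nothing changed 0 of 14358 genes were called. Genes were drawn independently of each other, without shifts of whole chromosomes or related lines, so these shares and counts do not cover such structure.

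Alternatives chosen with the plan were RLE size factors, no low-count filter, a stricter filter (CPM of 1 in 3 lines), each library as a replicate without and with the letter as a block, voom with the line as a random effect, a fit of the 2 genotypes alone, and leaving out each line and each letter. Added after the data were seen were no composition factor, voom on reads summed per line, removal of the local chromosomal median (30 genes on each side, log2 CPM of at least 2), the level of the start of chromosome 1 or of chromosome 13 as a covariate, a fit of only the lines of lower or of higher chromosome 13, library Wt4C left out, and lines 4 and 15 left out together. A stricter call, chosen with the plan, also needed at least a 2-fold change. Plots were drawn with matplotlib 3.10.9.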

Results

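RNA was sequenced from 13 HEK293T lines, a human embryonic kidney cell line that carries the large T antigen, edited at AFF3 with CRISPR-Cas9. AFF3 encodes a transcription elongation factor of the AFF family, whose members are scaffolds of super elongation complexes. The lines fell into 5 genotypes: 3 wild-type lines (Wt1, Wt2 and Wt4), 2 DN/DN lines (54 and 90), 5 LoF/LoF lines (4, 15, 20, 98 and 216), 2 DN/LoF lines (51 and 86) and 1 LoF/+ line (line 1). DN stands for the knock-in of the alanine-to-threonine change at residue 233 (A233T), an allele of KINSSHIP syndrome, and LoF for the knock-out allele. Each line was grown in biological triplicate, which gave 39 libraries. The genes of the table held 17851969 to 31904826 reads per library, with 3 libraries per line. The line was the unit of replication, so every n below counts lines, every ± after a mean is the SD between lines and every ± after a log2 fold change is its standard error. The labels do not give the derivation of the lines. Lines 4 and 15 had 19 chromosomal blocks of genes shifted in that pair alone, and lines 20 and 98 had 12. The independence of the LoF/LoF lines is therefore not known, and their n may overstate it.

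The edited gene was examined first, to see how far its RNA follows the genotypes. AFF3 (ENSG00000144218.21, GRCh38.p14 chromosome 2, 99545419 to 100142590) was lowest in the LoF/LoF lines, at 1.55 ± 0.44 log2 CPM (n = 5) against 4.16 ± 0.38 in wild type (n = 3). This is 17% of the wild-type mean CPM, with the lines between 9.82% and 22.8%. The LoF/+ line held 56.3%, the DN/LoF lines 47.7% (34.6% and 60.7%) and the DN/DN lines 89.4% (67.7% and 111%), while the wild-type lines themselves ran from 74% to 128%. In limma AFF3 fell in LoF/LoF against wild type by 2.60 ± 0.31 on the log2 scale (adjusted p = 0.0111), with all 5 lines below all 3 wild-type lines. The other log2 fold changes against wild type were -1.15 ± 0.38 in DN/LoF (adjusted p = 0.778), -0.84 ± 0.48 in LoF/+ (adjusted p = 1) and -0.29 ± 0.38 in DN/DN (adjusted p = 0.843). The lone LoF/+ line is assumed to vary like the lines of the other genotypes. AFF3 was 2.32 ± 0.35 higher in DN/DN than in LoF/LoF (adjusted p = 0.0469). It differed by 1.45 ± 0.35 in DN/LoF against LoF/LoF (adjusted p = 0.492) and by -0.87 ± 0.42 in DN/LoF against DN/DN (adjusted p = 0.832). With 1 line or letter left out these 2 values ran from 1.02 to 1.88 and from -1.29 to -0.44. AFF3 was named before the data were examined, so its limma p without adjustment over all genes is given too. Against wild type it was 0.00954 in DN/LoF and 0.467 in DN/DN. For DN/LoF it was 0.00105 against LoF/LoF and 0.0584 against DN/DN. The LoF/LoF call had adjusted p = 0.0523 without line 20, 0.0603 without Wt1 and 0.0559 without Wt2, at log2 fold changes of -2.65, -2.43 and -2.58, and 0.0766 (-2.81) in a fit of only the 8 lines in which chromosome 13 was not lower. The DN/DN value became 0.04 without line 90 and -0.62 without line 54, and the DN/LoF value was -0.73 without line 86. In lines 4 and 15 the neighbours of AFF3 also lay lower, with medians of -0.48 and -0.49. The counts cover the whole gene, so they do not tell edited from unedited transcripts.

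**Figure D1:**
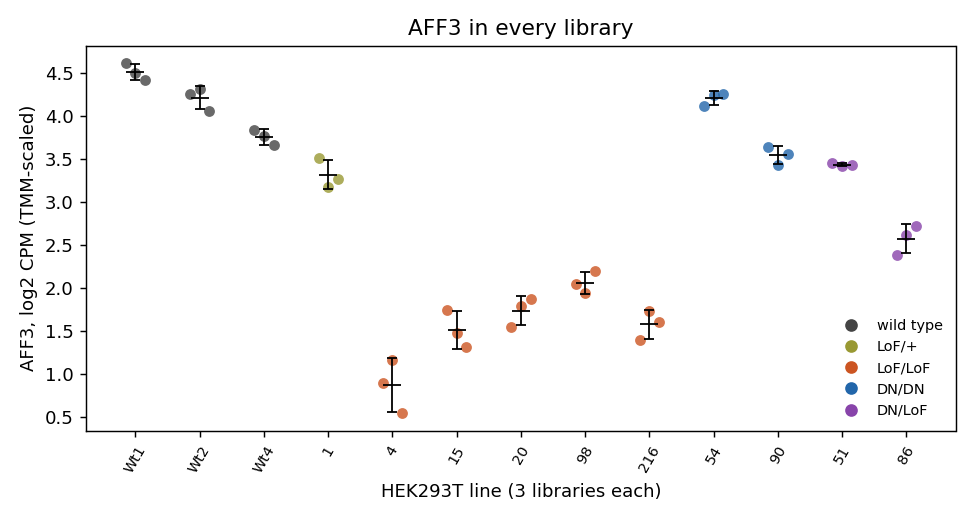
AFF3 level in each library (points, log2 CPM with TMM scaling) for the 13 lines along the horizontal axis, with bars for the mean and SD of the 3 libraries of a line. The 5 LoF/LoF lines lie between 0.87 and 2.06, below every other line, of which line 86 is lowest at 2.58.

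The paralogs of AFF3 were read next. AFF1 and AFF4, scaffolds of super elongation complexes, differed from wild type by -0.44 to 0.19 and by 0.00 to 0.27 on the log2 scale in the 4 mutant genotypes, and neither passed the test. AFF2, the gene of the FRAXE form of intellectual disability, was unevenly expressed among lines, with 112 reads in line 15, 130 in line 1, 204 in Wt1 and 123 in Wt2 against 1644 to 5417 in the other lines. Its log2 fold changes against wild type were 3.12 ± 1.59 in DN/DN, 1.67 ± 1.27 in LoF/LoF, 2.43 ± 1.59 in DN/LoF and -1.57 ± 2.01 in LoF/+, with adjusted p between 0.567 and 1. With 1 line or letter left out these ran from 2.28 to 4.49, 0.83 to 3.04, 1.59 to 3.80 and -2.41 to -0.20. Over all settings the lowest values were -0.21 in DN/DN and -0.48 in DN/LoF, so the direction of these 2 is not settled. Wt4 held 38.5 CPM of AFF2, against 2.72 in Wt1 and 1.7 in Wt2.

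LoF/LoF against wild type asks what the loss of AFF3 does. Besides AFF3, NREP and MAGEA12 fell. NREP (ENSG00000134986.14, chromosome 5, 111728802 to 111976932), which encodes neuronal regeneration related protein, fell by 1.27 ± 0.18, from 5.61 ± 0.16 log2 CPM in wild type (n = 3) to 4.34 ± 0.09 (n = 5; adjusted p = 0.0448), with all 5 lines below all 3. MAGEA12 (ENSG00000213401.10, chromosome X, 152733757 to 152737669), a cancer-testis antigen, had 2, 0, 0, 6 and 3 reads in lines 4, 15, 20, 98 and 216 against 46, 629 and 395 in Wt1, Wt2 and Wt4. The fitted fall of 4.92 ± 0.72 (adjusted p = 0.0448) depends on the prior count. Reads of MAGEA12 can be shared with near-identical paralogs, so this gene is uncertain. Neither low level was confined to LoF/LoF. NREP was at 22.1 CPM in DN/DN line 90, where its chromosomal neighbours lay at -0.45, against 19 to 22.2 CPM in LoF/LoF. In lines 1, 54, 51 and 86 NREP was at 35.1 to 40.7 CPM. MAGEA12 had 2, 0 and 7 reads in lines 51, 86 and 54, and 44 in line 90. Of 14347 genes limma called 3, all lower, with 1076 at an unadjusted p under 0.05 (638 higher, 438 lower) and 757 genes without overlap between the groups (5.3%, where chance gives 3.57%). The NREP call had adjusted p = 0.0832 without line 4, 0.12 without line 15, 0.177 without line 20, 0.1 without line 216, 0.221 without Wt1, 0.218 without Wt2 and 0.175 without Wt4, and MAGEA12 0.0832, 0.138, 0.233 and 0.106 without lines 4, 15, 20 and 216, 0.245 without Wt2 and 0.318 without Wt4; both had 0.0631 without the libraries of letter B. The count was 0 without line 20 or Wt2, 1 without line 4, line 15, Wt4 or letter B, and 7 without line 98, while the 1 gene was AFF3 each time.

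Gene lists in LoF/LoF moved together in 6 of 33 cases by limma's camera with its preset correlation, 4 higher and 2 lower. The immediate early genes, transcription factors and phosphatases induced within minutes of a stimulus, rose as a list with a median of 0.37 on the log2 scale, and 27 of 31 members lay above 0 (adjusted p = 2.5e-05). With an estimated correlation this list and the other 5 had adjusted p = 0.784. JUNB, an AP-1 subunit, was 1.66 ± 0.32 higher and was the 1 member called when adjusted over the list alone (p = 0.00462), with 0 called over all genes. IER2 was at 0.58, DUSP5 at 1.42 and DUSP1 at 0.50. Genes of G2 and M phase fell as a list, with a median of -0.20 and 45 of 56 members below 0 (adjusted p = 0.000643). Among them the spindle gene CKAP2L was at -0.61, the cytokinesis gene ANLN at -0.47 and the checkpoint kinase gene BUB1 at -0.38. RANGAP1 was at 0.32, and 0 members passed either adjustment. The list medians of lines 4, 15 and 20 were -0.17, -0.14 and -0.28. Those of lines 98 (-0.02) and 216 (-0.05) lay within the range of Wt1, Wt2 and Wt4 (0.09, -0.04 and -0.08). Library Wt4C alone was at -0.19. Cancer-testis antigens were lower as a list, with 11 of 16 members below 0 (adjusted p = 0.00317) and MAGEA12 as the 1 member called over all genes and adjusted over the list alone. The calls for replication-dependent histones (median 0.30, 11 of 11 above 0, adjusted p = 0.0293), p53 targets (0.25, 20 of 28, adjusted p = 0.0294) and ATF4 targets (0.17, 26 of 36, adjusted p = 0.0294) were weaker, again with 0 members called either way, and each had adjusted p = 0.0584 with the log2 values as deposited. With lines 4 and 15 left out together the p was 0.9 for ATF4 targets and 0.1 for histones. Cancer-testis antigens had adjusted p = 0.0728 without Wt4, ATF4 targets 0.385 without line 4, 0.165 without line 15, 0.105 without Wt1 and 0.36 without Wt4, and histones 0.0831 without line 15, 0.166 without line 216, 0.712 without Wt2 and 0.116 without letter C. The p53 targets had 0.17, 0.124 and 0.299 without lines 15, 20 and 216, 0.171 without Wt1, 0.399 without Wt4, 0.116 without letter C and 0.0679 without library Wt4C.

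DN/DN against wild type asks what 2 copies of the dominant-negative allele do. No gene passed the test, so the genes with the smallest p are given as values, each with adjusted p = 0.437. On the higher side were RAC2, a small GTPase of blood cells (2.91 ± 0.58, 2.28 against 0.22 CPM), C1QTNF1, a secreted C1q-related protein (2.08 ± 0.41), DOK4, an adaptor of receptor tyrosine kinases (1.64 ± 0.33), and CACNG7, a calcium channel gamma subunit. CACNG7 had 246 and 44 reads in lines 54 and 90 against 4, 1 and 0 in Wt1, Wt2 and Wt4. On the lower side was PSMD5, an assembly chaperone of the proteasome, with 1 and 2 reads in lines 54 and 90 against 120, 535 and 1326 in Wt1, Wt2 and Wt4, a ratio of 477 (95% exact counting interval 163 to 2310). The other 4 lie on chromosome 14: the nuclear kinase gene VRK1 (-0.87 ± 0.15), PPP2R5C of protein phosphatase 2A (-0.73 ± 0.15), the HSP70 co-chaperone gene BAG5 (-0.68 ± 0.15) and the glycogen phosphorylase gene PYGL (-1.35 ± 0.30). PYGL was at 6.43 log2 CPM in line 54 and 7.48 in line 90. Its log2 fold change ran from -1.88 to -0.83 with 1 line or letter left out. The median of chromosome 14 was -0.48 in line 54 and -0.01 in line 90, but in line 90 the neighbours of VRK1, PPP2R5C and BAG5 lay at -0.32, -0.42 and -0.56. With the local chromosomal median removed the 3 genes were at -0.44, -0.28 and -0.19. Limma on the line means called 0 of 14347 genes, with 1319 at an unadjusted p under 0.05 (717 higher, 602 lower). limma voom called 0 on reads summed per line and 182 with the line as a random effect, while limma on the log2 values with each library as a replicate called 4102. Of the 14347 genes, 3865 did not overlap between the 2 and 3 lines (26.9%, where chance gives 20%). The count was 11 without line 90 and 1 without line 54 (CTSF), Wt1 (PSMD5) or Wt4 (RIOX1). Genes named for such a run alone, here and below, were chosen after their values were seen.

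As lists, the DN/DN lines were lower in ribosomal and cell cycle genes and higher in ATF4 targets and blood cell markers, with 10 lists called higher and 7 lower of 33. Cytosolic ribosomal protein genes fell with a median of -0.37, and 74 of 80 members lay below 0 (adjusted p = 2.16e-14, and adjusted p = 0.275 with an estimated correlation). RPL21 was at -0.71, RPS18 at -0.69, RPL7 at -0.69 and RPL5 at -0.63. Many ribosomal protein genes share reads with processed pseudogenes and are uncertain one by one. Genes of S phase (median -0.30, 50 of 56 below 0) and of G2 and M phase (-0.25, 53 of 56) fell as well (adjusted p = 1.37e-07 each, and 0.275 and 0.238 with an estimated correlation). The DNA polymerase gene POLA1 was at -0.78, the replication clamp gene PCNA at -0.54, the CDK-binding gene CKS2 at -0.68 and the spindle assembly gene TPX2 at -0.46. ATF4 targets, the genes of the integrated stress response, rose with a median of 0.60 and 32 of 36 members above 0 (adjusted p = 1.71e-07, and adjusted p = 0.288 with an estimated correlation). PCK2, a mitochondrial enzyme of gluconeogenesis, was at 1.20, the glutathione-degrading CHAC1 at 1.93, the glycine transporter SLC6A9 at 1.20 and DDIT3, which encodes CHOP, at 1.03. The numbers called over all genes and adjusted over the list alone were 0 for each of these 4 lists. Blood cell markers were higher, with all 5 measured members above 0 (adjusted p = 5.56e-05, and adjusted p = 0.0961 with an estimated correlation). RAC2 and the actin regulator CORO1A (1.04) were among those called when adjusted over the list alone, and 0 members were called over all genes. Without line 54 the ATF4 call was lost (adjusted p = 0.243), and the list medians by line were 1.03 in line 54 and 0.19 in line 90. The S phase medians were -0.42 and -0.12 in lines 54 and 90, and those of G2 and M phase -0.36 and -0.11. The ribosomal medians were -0.54 in line 54 and -0.15 in line 90, against -0.13, 0.10 and 0.04 in Wt1, Wt2 and Wt4.

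Neuronal and matrix genes were the other side of the DN/DN lists. Neuronal and synaptic genes (median 0.35, 38 of 51 above 0), axon guidance genes (0.34, 46 of 65) and extracellular matrix genes (0.36, 49 of 67) rose together, each with adjusted p = 0.0016, and adjusted p = 0.222 with an estimated correlation. Fibroblast markers, of another cell type, were higher too (median 0.54, adjusted p = 0.0399, and 0.238 as the p with an estimated correlation), at 0.68 in line 54 and 0.32 in line 90. The presynaptic adhesion gene NRXN2 was at 1.81, the neuronal splicing factor gene RBFOX3 at 2.02, the semaphorin gene SEMA6B at 1.47 and the protease inhibitor gene TIMP2 at 1.27, while COL3A1 of the matrix list was at -3.48, and 0 members of the neuronal, axon and matrix lists passed either adjustment. Cartilage, bone and limb genes (median 0.23, 31 of 43 above 0, adjusted p = 0.00373, and 0.238 as the p with an estimated correlation) included the cartilage proteoglycan gene ACAN at 2.33 and COMP at 1.69. Heat shock proteins fell as a list (median -0.24, 14 of 17 below 0, adjusted p = 0.00528, and 0.288 as the p with an estimated correlation). Adjusted over the list alone, HSPA8 (-0.72, p = 0.00708), HSP90AA1 (-0.69, p = 0.00708) and HSPB1 (1.55, p = 0.0138) were called, and 0 over all genes. Cholesterol synthesis genes were lower (median -0.25, 20 of 25 below 0, adjusted p = 0.00929, and 0.436 as the p with an estimated correlation), with FDPS, which encodes farnesyl diphosphate synthase, at -0.60. Without line 54 the calls of the axon (adjusted p = 0.166), neuronal (0.0915), matrix (0.0686), heat shock (0.0686) and cholesterol (0.498) lists were lost, and without line 90 that of the cartilage list (0.0812). The heat shock call was also lost with the local chromosomal median removed (0.0818).

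**Figure D2:**
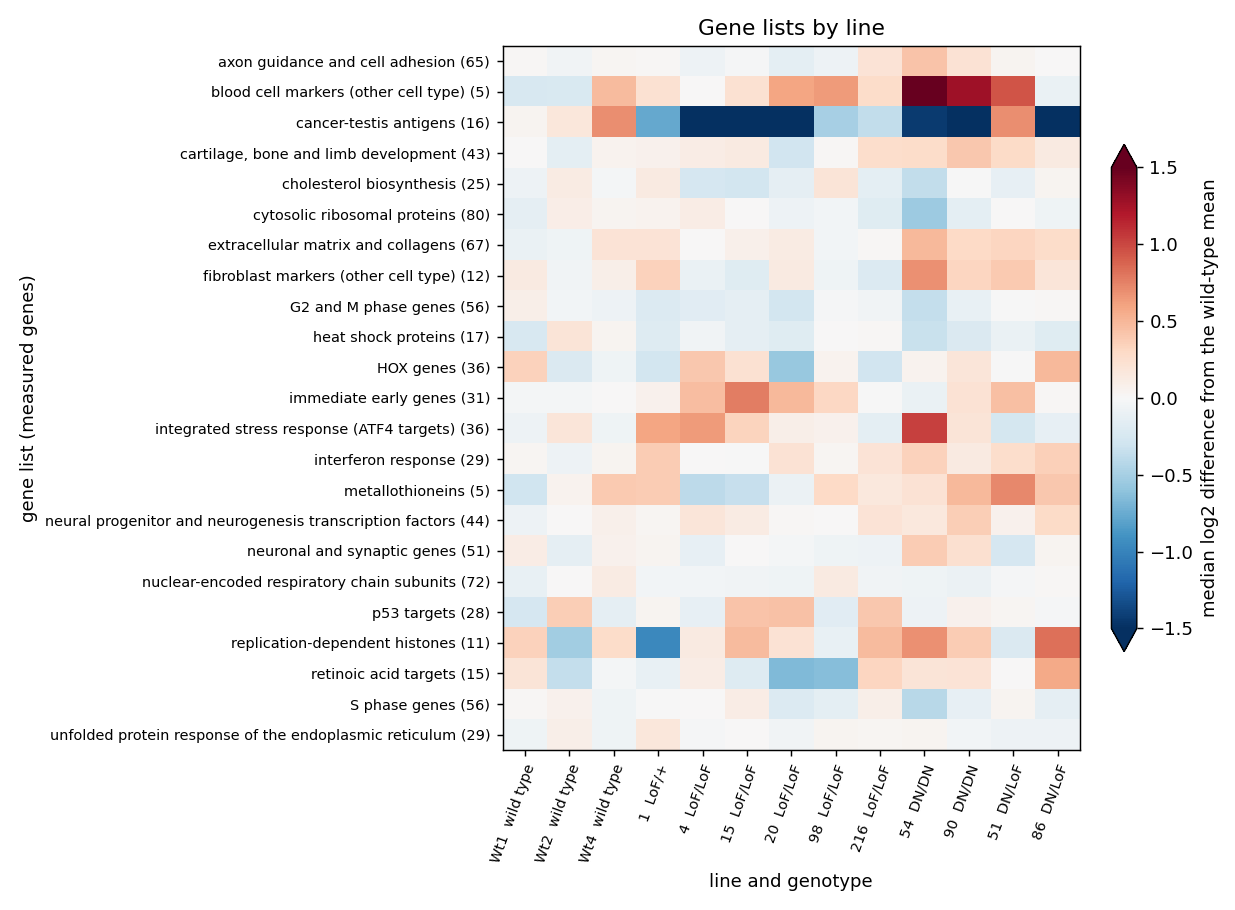
Heat map of the median log2 difference from the wild-type mean for the 23 gene lists called in at least 1 comparison (vertical axis) in the 13 lines (horizontal axis), with colours that stop at ±1.5 and end colours beyond. Line 54 stands apart from line 90 for ATF4 targets (1.03 against 0.19) and ribosomal proteins (-0.54 against -0.15), and members with few reads sit near the floor of the log2 scale.

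DN/LoF against wild type asks what 1 dominant-negative copy over a null copy does. The long noncoding RNA LINC01036 (ENSG00000230426.5, chromosome 1, 187092842 to 187360244) fell in both lines, with 1 and 2 reads in lines 51 and 86 against 499, 537 and 197 in Wt1, Wt2 and Wt4. The ratio was 258 (95% exact counting interval 88.1 to 1250), and the fitted log2 fold change of -5.72 ± 0.52 (adjusted p = 0.000554) depends on the prior count. The call was lost with limma voom on summed reads (-7.57, adjusted p = 0.677) or with the line as a random effect (-7.13, 0.0879) and with the level of chromosome 13 as a covariate (-4.96, 0.108). It was also lost in a fit of the 2 genotypes alone (-5.72, 0.0976) and in a fit of only the lines of lower chromosome 13 (-4.76, 0.978), where wild type is 1 line. Interferon response genes rose as a list, with a median of 0.38 and 26 of 29 members above 0 (adjusted p = 0.00479, and adjusted p = 0.403 with an estimated correlation). IFI35 was at 2.27 and TAP1, a subunit of the antigen peptide transporter, at 0.68, and 0 members passed either adjustment. Cancer-testis antigens were lower (12 of 16 below 0, adjusted p = 0.0115, and 0.403 as the p with an estimated correlation), and MAGEA12 was called when adjusted over the list alone (p = 0.00101), with 0 over all genes. Extracellular matrix genes (median 0.21, 45 of 67 above 0, adjusted p = 0.0377), HOX genes (0.29, 30 of 36, adjusted p = 0.0377) and immediate early genes (0.22, 19 of 31, adjusted p = 0.0386) were higher, with p values of 0.403, 0.747 and 0.61 with an estimated correlation. JUNB was at 1.69 and was called when adjusted over the list alone (p = 0.0291), with 0 over all genes. FOSL1, another AP-1 subunit, was at 2.47, the matrix protease gene ADAMTS1 at 0.97 and HOXD1 at 1.08. With the log2 values as deposited the matrix, HOX and immediate early calls had adjusted p = 0.104 each. Limma called 1 gene, with 891 at an unadjusted p under 0.05 (413 higher, 478 lower) and 4066 without overlap (28.3%, where chance gives 20%), and the count was 5 without line 51 (with SNAI2, LAS1L, SLC7A3 and BEX4) and 2 without Wt1 (with MAGEA12) or Wt4 (with RIOX1). The list calls lost were cancer-testis without line 86 (adjusted p = 0.755) or Wt4 (0.147), matrix without line 51 (0.13), Wt2 (0.111) or letter B (0.0779), HOX without line 86 (0.867), Wt2 (0.349) or Wt4 (0.216), and immediate early without line 51 (0.503), Wt2 (0.0751), Wt4 (0.147) or letter B (0.0779).

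LoF/+ against wild type asks what the loss of 1 copy does, in 1 line, which is assumed to vary like the lines of the other genotypes. Replication-dependent histones were lower in this line, with a median of -0.97 and all 11 members below 0 (adjusted p = 8.63e-09, and adjusted p = 0.66 with an estimated correlation). H1-2 was at -1.79, H2BC11 at -1.50, H4C8 at -1.39 and H3C10 at -1.21. Most transcripts of these genes lack a poly(A) tail, which the library kit selects for, and the list medians of Wt1, Wt2 and Wt4 spread over 0.34, -0.52 and 0.27. ATF4 targets were higher, with a median of 0.59 and 34 of 36 members above 0 (adjusted p = 3.17e-08, and 0.721 as the p with an estimated correlation). PCK2 was at 1.57 and CHAC1 at 2.07. Lines of other genotypes reached similar ATF4 medians, 0.64 in line 4 and 1.03 in line 54, and the p values of 1 line do not separate its genotype from its own state. Genes of G2 and M phase were lower (median -0.21, 41 of 56 below 0, adjusted p = 0.00466, and 0.749 as the p with an estimated correlation), with the lamin B receptor gene LBR at -0.90. Interferon response genes (0.38, 22 of 29 above 0, adjusted p = 0.035) with HLA-E at 0.81, and unfolded protein response genes (0.17, 21 of 29 above 0, adjusted p = 0.035) with CRELD2 at 0.67, were higher, and HOX genes were lower (-0.27, 30 of 36 below 0, adjusted p = 0.0376). With an estimated correlation the p values were 0.66, 0.66 and 0.845. The numbers called over all genes and adjusted over the list alone were 0 in all 6 lists. The interferon, unfolded protein and HOX calls were lost without library Wt4C (adjusted p = 0.0657 each). The interferon call was lost without Wt2 (adjusted p = 0.146) or letter B (0.0623) and with the stricter filter (0.0509), the unfolded protein call without Wt1 (0.0536), Wt4 (0.135) or letter B (0.0618), and the HOX call without Wt1 (0.398) or letter B (0.0618), with the stricter filter (0.0509) and with the local chromosomal median removed (0.0865).

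No single gene passed the test in LoF/+, and the genes with the smallest p are values. On the lower side were TPTEP1, a noncoding gene, with 0 of 65186573 reads in line 1, the long noncoding RNA LINC01535 (adjusted p = 0.11) with 3 reads, the mechanosensitive channel gene PIEZO2 with 1 read, MNS1, a gene of meiosis and cilia (-3.43 ± 0.60), and FBXO21, an F-box subunit of a ubiquitin ligase (-1.26 ± 0.23), the other 4 each with adjusted p = 0.304. A count of 0 allows up to 0.046 CPM for TPTEP1 (3 reads over the line), which is at least 209-fold lower than the wild-type mean of 9.61 CPM. The ratio to wild type was 58.7 for LINC01535 (95% exact counting interval 20 to 286) and 169 for PIEZO2 (30.1 to 6670). On the higher side, each with adjusted p = 1, were the cancer-testis genes MAGEA12 (4.51 ± 1.14) and CSAG1 (4.87 ± 1.28), the phospholipase gene PLCD3 (0.97 ± 0.25), the Ras-association gene RASSF7 (1.25 ± 0.33) and SERINC2, which encodes a serine incorporator (1.24 ± 0.33). MAGEA12 had 4759 reads in line 1. Limma on the line means called 0 genes with 513 at an unadjusted p under 0.05 (295 higher, 218 lower), while limma voom called 0 on summed reads and 4 with the line as a random effect. On the log2 values with each library as a replicate limma called 1509. Without overlap were 7808 genes (54.4%, where chance gives 50%), and without Wt2 the count was 2, PIEZO2 and LINC01535.

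DN/DN against LoF/LoF asks whether the dominant-negative allele acts differently from loss, and 4 genes were called. The DN/DN lines also differed from the LoF/LoF lines in the median of chromosome 13 (-0.34 and -0.38 against 0.03 to 0.17). This comparison alone therefore does not tell the allele from that background. With the level of chromosome 13 as a covariate all 4 calls were lost (limma, adjusted p = 0.998 each). NRG4 (ENSG00000169752.17, chromosome 15, 75935393 to 76060240), a neuregulin that binds ERBB4, was 1.80 ± 0.27 higher in DN/DN, at 2.29 ± 0.06 log2 CPM (n = 2) against 0.50 ± 0.13 (n = 5; adjusted p = 0.0469), with both lines above all 5. Its mean was 5.1 CPM in DN/DN, 1.35 in LoF/LoF and 3.63 in wild type. VRK1 (ENSG00000100749.9, chromosome 14, 96797382 to 96881609) fell, with a log2 fold change of -0.99 ± 0.14, at 5.76 ± 0.15 log2 CPM (n = 2) against 6.76 ± 0.11 (n = 5; adjusted p = 0.0465). With the median of its chromosomal neighbours removed from each line this became -0.56 (adjusted p = 0.19). Over the settings the adjusted p ran from 2.7e-15 to 0.998. Of the 24 settings 1 also needed at least a 2-fold change, which VRK1 missed at -0.99. PSMD5 (ENSG00000095261.14, chromosome 9, 120816053 to 120842922) had 3 reads in the 2 DN/DN lines against 6145 in the 5 LoF/LoF lines, a ratio of 931 (95% exact counting interval 318 to 4520), with a fitted log2 fold change of -7.33 ± 0.89 (adjusted p = 0.0465). AFF3 itself was the other gene, 2.32 ± 0.35 higher (adjusted p = 0.0469). Beside these 4 genes (2 higher, 2 lower), 1471 had an unadjusted p under 0.05 (711 higher, 760 lower) and 1847 did not overlap (12.9%, where chance gives 9.52%). All 4 calls were lost without line 4 (adjusted p = 0.113 each), line 15 (0.108 to 0.134), line 20 (0.0951 to 0.137), line 216 (0.0753 each), line 54 (0.46 to 0.475) or letter A (0.0501 to 0.136) or C (0.0612 to 0.114). Those of NRG4 (0.0784) and VRK1 (0.0527) were lost without line 98, those of AFF3 (0.0505), NRG4 (0.0696) and PSMD5 (0.0674) without line 90, and that of AFF3 (0.0556) without letter B. The count was 0 without line 4, 15, 20 or 216 or letter A or C, 1 without line 54 (CTSF) and 20 without line 90.

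**Figure D3:**
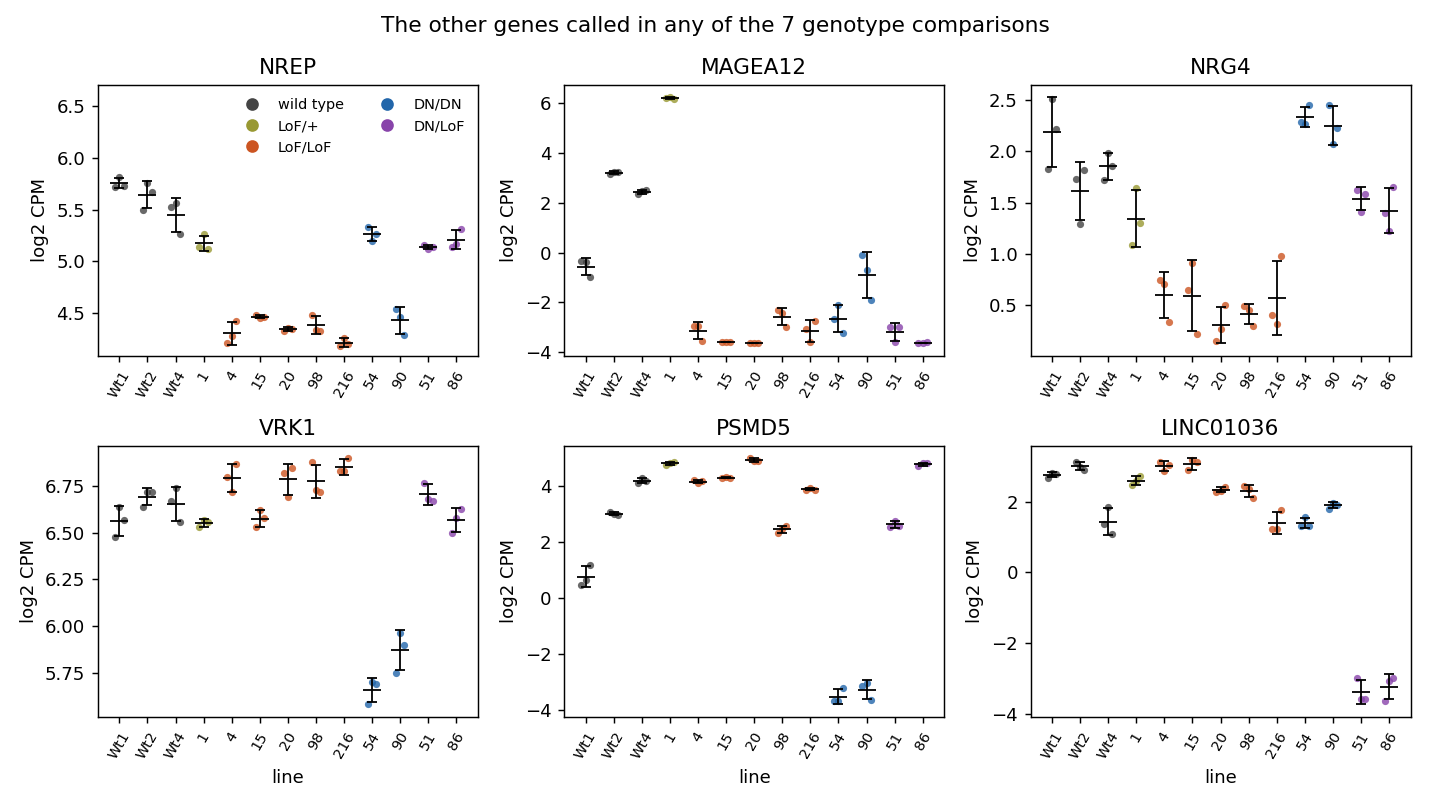
Levels of NREP, MAGEA12, NRG4, VRK1, PSMD5 and LINC01036 in each library (points, log2 CPM with TMM scaling) for the 13 lines, with bars for the mean and SD of the 3 libraries of a line. PSMD5 lies near the floor in lines 54 and 90 and LINC01036 in lines 51 and 86, while VRK1 in lines 54 and 90 lies at a mean of 5.76 against 6.76 in LoF/LoF.

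In DN/DN against LoF/LoF, 15 lists were called, 10 higher and 5 lower. Cytosolic ribosomal proteins fell (median -0.30, 76 of 80 below 0, adjusted p = 3.51e-12, and 0.4 as the p with an estimated correlation), and RPL21 (-0.70) and RPL7 (-0.73) were called when adjusted over the list alone (p = 0.0377 each). Blood cell markers were higher (median 1.43, 5 of 5 above 0, adjusted p = 0.000772, and 0.153 as the p with an estimated correlation), with RAC2 at 2.52 called when adjusted over the list alone. S phase genes fell (median -0.23, 49 of 56 below 0, adjusted p = 1.45e-06, and 0.4 as the p with an estimated correlation), and PCNA (-0.77), the replication helicase gene GINS1 (-0.68) and POLA1 (-0.64) were called when adjusted over the list alone. Neuronal genes (median 0.51, 43 of 51 above 0, adjusted p = 0.000274), axon guidance genes (0.37, 51 of 65, adjusted p = 0.000772) and fibroblast markers (0.77, 9 of 12, adjusted p = 0.00298) rose, with p values of 0.153, 0.194 and 0.153 with an estimated correlation. The neurofilament gene NEFM was at 2.29 and the guidance gene SEMA3A at 1.51. Adjusted over the list alone, 4 fibroblast markers were called, the collagen gene COL1A1 (1.32), the proteoglycan gene LUM (2.42), the growth factor receptor gene PDGFRA (1.12) and the homeobox gene PRRX1 (3.98). Over all genes 0 members of these 6 lists were called. Retinoic acid targets (median 0.57, 13 of 15 above 0) and HOX genes (0.28, 32 of 36) were higher, each with adjusted p = 0.00457, and with p values of 0.4 and 0.531 with an estimated correlation, and RARG was at 0.91 and CRABP2 at 2.54. Lost without line 54 were the S phase (adjusted p = 0.122), neuronal (0.0744), axon (0.195) and fibroblast (0.164) calls. The HOX call was lost without line 20 (0.127) or 90 (0.117) and with the local chromosomal median removed (0.845), and the retinoic call without line 98 (0.0539) or 90 (0.0713).

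DN/LoF was also set against each homozygous mutant, to set the effect of each allele apart. Against LoF/LoF this is limited, since chromosome 13 was also lower in lines 51 and 86 (-0.38 and -0.24 against 0.03 to 0.17). LINC01036 fell against both homozygous mutants. It had 3 reads in the 2 DN/LoF lines against 1993 in LoF/LoF, a ratio of 263 (95% exact counting interval 89.7 to 1270; fitted log2 fold change -5.75 ± 0.48, adjusted p = 0.000175), and against 514 in DN/DN, a ratio of 149 (50.7 to 725; -4.96 ± 0.57, adjusted p = 0.00927). Against LoF/LoF, HOX genes were higher (median 0.33, 30 of 36 above 0, adjusted p = 0.00301) and ATF4 targets lower (-0.38, 27 of 36 below 0, adjusted p = 0.00521), each with p = 0.645 with an estimated correlation, and HOXD11 was at 0.81 and CEBPG at -0.80. Against DN/DN, ribosomal proteins were higher (median 0.32, 69 of 80 above 0, adjusted p = 1.73e-11, and 0.487 as the p with an estimated correlation). Genes of G2 and M phase (0.25, 51 of 56, adjusted p = 8.82e-07) and of S phase (0.20, 49 of 56, adjusted p = 9.59e-05) were also higher, with p values of 0.42 and 0.579 with an estimated correlation. ATF4 targets were lower (-0.69, 33 of 36 below 0, adjusted p = 1.32e-10, and 0.42 as the p with an estimated correlation), with CHAC1 at -2.35. Neuronal genes (-0.54, 39 of 51 below 0, adjusted p = 1.26e-05), axon guidance genes (-0.29, 48 of 65, adjusted p = 9.88e-05) and blood cell markers (-0.77, 4 of 5, adjusted p = 0.00526) were lower, each with p = 0.164 with an estimated correlation. Adjusted over the list alone, the adhesion gene L1CAM (-2.68), RAC2 (-2.75) and CD34 (-2.11) were called, and over all genes 0 members of these lists. Limma called 1 gene in each comparison, with 1202 and 843 genes at an unadjusted p under 0.05. The LINC01036 call against LoF/LoF was lost with limma voom on summed reads (log2 fold change -7.58, adjusted p = 0.382) and with the level of chromosome 13 as a covariate (-4.85, 0.218). Against DN/DN it was lost with limma voom on summed reads (0.549) or with the line as a random effect (0.168). It was also lost there in a fit of the 2 genotypes alone (0.266) and of only the lines of lower chromosome 13 (log2 fold change -4.96). The call against DN/DN was lost without line 54 (adjusted p = 0.0764), 51 (0.0628) or 86 (0.164), where the 1 gene called was CTSF without line 54 and SLC7A3 without line 51, and 0 genes were called without line 86 and 15 without line 90. Against LoF/LoF the count was 6 without line 51, 4 without line 216 (with LINC00662, PPP1R15A and ARMCX4) and 2 without line 4 (with SLC16A14), line 20 or letter A (both with GPR50). List calls lost were HOX without line 20 (0.0865) or 86 (0.237) or with the local chromosomal median removed (0.137), ATF4 without line 51 (0.069) or without lines 4 and 15 together (0.217) against LoF/LoF, and, against DN/DN, ATF4, axon and G2 and M without line 54 (0.064 each), S phase without line 54 (0.434) or 51 (0.128), and blood without line 90 (0.125) or 86 (0.115) or with the stricter filter (0.495).

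The direction of the DN and LoF effects was compared across genes, which are not independent replicates. Over 14347 genes the log2 fold changes of DN/DN and LoF/LoF against wild type had a Pearson correlation of r = 0.40 and a Spearman correlation of 0.40. In the alternative settings this r ran from 0.19 to 0.61. Unchanged groups simulated against the same wild-type lines gave r = 0.46 on average over 1000 draws (-0.26 to 0.91). The covariance was 0.089, against 0.085 simulated, a difference of 0.004. Of these draws 63.6% had an r and 40.8% a covariance at least as large as observed. No gene could be called in both comparisons, since DN/DN against wild type called 0 genes. At an unadjusted p under 0.05, 149 genes were higher in both (31.9 for independent lists), 53 were lower in both (18.4) and 5 went opposite ways. For DN/DN and DN/LoF r was 0.49 (0.37 simulated, -0.39 to 0.87) with a covariance of 0.135 (0.083 simulated), and for LoF/LoF and DN/LoF r was 0.36 (0.49 simulated, -0.26 to 0.88) with a covariance of 0.071 (0.088 simulated). The 3 wild-type lines cannot be split so that each part keeps more than 1 line, and the numbers for independent lists make no allowance for the shared controls.

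Lines differed from one another about as much within a genotype as between genotypes. The root mean square log2 difference was 0.717 between lines of 1 genotype (15 pairs) and 0.737 between lines of different genotypes (permutation p = 0.262, one-sided, 100000 permutations), against 0.302 between libraries of 1 line. The nearest line had the same genotype for 3 of 13 lines, where permutations gave a mean of 2.51. Lines 54, 90, 51, 86 and 98 lay nearest to Wt4. Whole chromosomes shifted line by line. The median of the 202 genes of chromosome 13 was lower in lines 54 (-0.34), 90 (-0.38), 51 (-0.38), 86 (-0.24) and Wt4 (-0.25) than in the other lines (0.03 to 0.24). The median of chromosome 2, where AFF3 lies, was -0.47 in line 4 and -0.45 in line 15. Chromosome 16 was at -0.67 in Wt1, and chromosome 9, where PSMD5 lies, was at -0.46 in line 54. Without Wt4, LoF/LoF against Wt1 and Wt2 left the AFF3 call (-2.81, adjusted p = 0.035) as the 1 gene called. In a fit of only the lines of higher chromosome 13, 0 genes were called there, with adjusted p = 0.0766 for AFF3 (-2.81) and NREP (-1.36). In a fit of only the lines of lower chromosome 13, where wild type is Wt4 alone and is assumed to vary like the other lines, 0 genes were called in DN/DN and in DN/LoF against wild type. AFF3 was at 0.12 in DN/DN (adjusted p = 0.999) and at -0.75 in DN/LoF (adjusted p = 1) in this fit, and LINC01036 at -4.76 in DN/LoF (adjusted p = 0.978). AFF3 was at 4.20 and 3.54 log2 CPM in lines 54 and 90, at 3.43 and 2.58 in lines 51 and 86, and at 3.76 in Wt4.

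**Figure D4:**
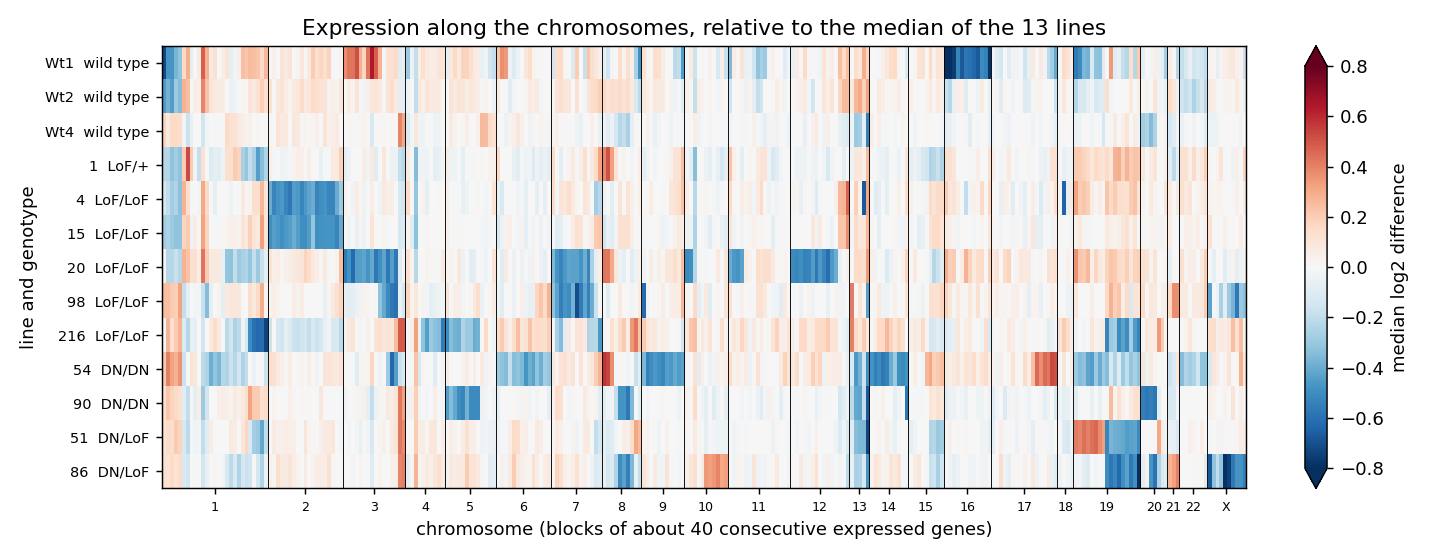
Median log2 difference from the median of the 13 lines for 276 blocks of about 40 expressed genes in genome order (horizontal axis) in each line (vertical axis), with colours that stop at ±0.8 and end colours beyond. Blocks beyond ±0.3 make up 22.8% of the blocks in line 54, 18.1% in line 20 and 14.1% in Wt1, against 1.1% in Wt4 and 2.2% in Wt2.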

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

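Apart from the count of splits of the samples with AFF3 included, the tests of explanations in this part were chosen after the results they address were seen. Among the 5 LoF/LoF lines, 4 genes had 1 line far from the other 4: VRK1 at 6.58 log2 CPM in line 15 (the next at 6.78), CSAG1 at -2.65 in line 98 (next -3.46), TPTEP1 at 2.22 in line 20 (next 3.62) and AFF2 at 0.79 in line 15 (next 4.70). Chance puts about 1 in 20 groups on this list, and 30 groups were checked. CSAG1 had 6 reads in line 98 and 0 or 1 in the other LoF/LoF lines, so its gap depends on the prior count. Tested differences between the DN and LoF genotypes were found for AFF3 (2.32), NRG4 (1.80), PSMD5 (-7.33) and VRK1 (-0.99) in DN/DN against LoF/LoF. For LINC01036 they were -5.75 in DN/LoF against LoF/LoF and -4.96 in DN/LoF against DN/DN.

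In LoF/LoF against wild type, limma called 3 genes. Of the 56 splits of these 8 lines into 5 and 3, 2 called as many, the real one included. AFF3 is the edited gene, so part of the real count was set by the knock-out, and the count cannot exclude chance. Besides AFF3, 4 of the 56 splits called at least 2 genes, so chance is not excluded for NREP and MAGEA12. The highest other split, lines 98, 216 and Wt4 against lines 4, 15, 20, Wt1 and Wt2, called 143 genes and follows the level of the start of chromosome 1, which points to a structure of the samples that is not their genotype.

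VRK1, BAG5 and PPP2R5C, which lie near each other on chromosome 14, were lower in both DN/DN lines. Copy number of the segment has the values it needs: the 59 expressed neighbours of VRK1 had a median log2 fold change of -0.50 in DN/DN against LoF/LoF, 51 of them below 0 (interquartile range -0.63 to -0.19), and they lay at -0.51 in line 54 and -0.32 in line 90. VRK1 lay lower than nearly all of them, with 1 neighbour as low. It was picked as a called gene of this comparison, which favours a low rank, so the rank cannot decide whether the segment is the whole cause. An effect of the DN allele on VRK1 alone cannot be told apart from the segment. With the local median removed the log2 fold change of VRK1 went from -0.99 ± 0.14 to -0.56 ± 0.10. The call ended there (adjusted p = 0.19, with 2.7e-15 to 0.998 over the settings). All 4 calls of the comparison ended in that fit (smallest adjusted p 0.0697), so the smaller fold and the change of the whole fit are not told apart. In DN/LoF against LoF/LoF VRK1 was at -0.12 ± 0.14, so 1 DN copy came with no such value, and an effect of 2 copies stays open.

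PSMD5 was near 0 in both DN/DN lines and LINC01036 in both DN/LoF lines. Chance coincidence of genes silent in single lines stays open: of the 76 pairs other than the 2 that prompted the question, 1 pair alone lacked a gene that the other lines expressed (LINC01806, named after its values were seen, in lines 4 and 98; Fisher's exact test, p = 0.17), too few to tell. Loss of a segment that spans the 59 expressed neighbours of PSMD5 is argued against for line 90, where they had a median of 0. In line 54 they lay at -0.44. A loss of PSMD5 alone or of a few genes would not move this median and was not tested. The neighbours of LINC01036 lay at 0 in line 51 and -0.15 in line 86. Shared ancestry of the lines of a genotype cannot be told apart from genotype, because the labels do not give the derivation of the lines; 1 block of genes was shifted in the DN/DN pair alone, and 1 in the DN/LoF pair, but 16 of the 78 pairs had at least as many, led by 2 LoF/LoF pairs, lines 4 and 15 with 19 and lines 20 and 98 with 12, against up to 6 in pairs of different genotypes. The DN/LoF lines, with 1 DN copy, kept PSMD5 (17.1 CPM) and the DN/DN lines kept LINC01036 (3.21 CPM), so an effect of 2 DN copies on PSMD5 and of the DN/LoF combination on LINC01036 stay open.

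Ribosomal protein genes were lower and ATF4 targets higher in DN/DN. For line 54 the state of single cultures at harvest is argued against, since all 3 libraries (ribosomal medians up to -0.41, ATF4 medians from 0.97) lay beyond every library outside DN/DN (-0.23 and 0.65), and so is a background shared with Wt4, since lines 51, 86 and Wt4, which share the lower chromosome 13, had a mean ribosomal median of -0.01 and ATF4 medians up to -0.07. For line 90 neither can be told apart: its libraries had ribosomal medians of -0.22 to -0.09, the lowest of lines 51, 86 and Wt4 was at -0.06, and the libraries of 1 line ranged by up to 0.18. A state shared by all 3 cultures of line 54, such as its growth rate, could account for part of the pattern and was not tested, as line 54 had -0.54 and line 90 -0.15. An effect of 2 copies of the DN allele also stays open.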

How the results depend on the processing

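Alternatives without a composition factor, with voom on summed reads, with the local chromosomal median removed, with a chromosome level as a covariate, with only the lines of lower or of higher chromosome 13 with library Wt4C left out and with lines 4 and 15 left out were added after the results were seen. Counts of called genes are given in the order DN/DN, LoF/LoF, DN/LoF and LoF/+ against wild type, then DN/DN and DN/LoF against LoF/LoF, then DN/LoF against DN/DN, where the limma fit on line means called 0, 3, 1, 0, 4, 1 and 1. Each library as a replicate called 4102, 3414, 2902, 1509, 4269, 3690 and 2668 genes, since libraries of 1 line vary less than lines. With the letter as a replicate block this became 3846, 3133, 2635, 1294, 4004, 3465 and 2431, but the letters share only a label: the deviations of same-letter libraries had a median r of -0.01 (-0.39 to 0.42), and 12 of 39 libraries lay closest to their own letter. In these fits AFF3 passed in DN/LoF (-1.15, with and without the replicate block) and in LoF/+ (-0.84, with and without it). Voom with the line as a random effect called 182, 17, 10, 4, 471, 175 and 6. A fit of the 2 genotypes alone called 1 in DN/DN and 0 in DN/LoF against wild type, 2 in DN/DN and 6 in DN/LoF against LoF/LoF, and 0 in DN/LoF against DN/DN. Voom on summed reads called 0 in each of the 3 DN/LoF comparisons. No composition factor left 1 call in LoF/LoF against wild type and moved the median log2 fold of all genes in DN/DN against wild type from -0.008 to 0.099. The start of chromosome 1 as a covariate left 1 there and 0 in DN/DN against LoF/LoF. Chromosome 13 as a covariate left 1 in LoF/LoF and 0 in DN/LoF against wild type. It left 0 in DN/DN and DN/LoF against LoF/LoF, where its level separates the genotypes and the lost calls decide nothing. A fit of only the lines of higher chromosome 13 left 0 in LoF/LoF against wild type, and a fit of only the lines of lower chromosome 13 left 0 in DN/LoF against wild type and against DN/DN. Removal of the local median left 0 in DN/DN against LoF/LoF, and lines 4 and 15 left out gave 2 there and 3 in DN/LoF against LoF/LoF. Library Wt4C left out changed no call of a gene against wild type and left 28 list calls. Leaving out 1 line or letter at a time gave 0 to 11, 0 to 7, 1 to 5, 0 to 2, 0 to 20, 1 to 6 and 0 to 15. AFF3 in LoF/LoF stayed between -2.81 and -2.43 in these runs and was lost at -2.65 without line 20, -2.43 without Wt1 and -2.58 without Wt2, and at -2.81 in the fit of only the lines of higher chromosome 13. AFF3 in DN/DN against wild type ran from -0.62 to 0.04 with lines and letters left out, reversed at 0.04 without line 90 and with chromosome 13 as a covariate, and at 0.12 with only the lines of lower chromosome 13. The correlation of DN/DN and LoF/LoF effects (0.40) ran from 0.31 without line 54 to 0.61 without Wt4 and was 0.19 with chromosome 13 as a covariate. List calls against wild type went from 34 to 0 with an estimated correlation and were 24 to 45 otherwise. NREP (-1.36 to -1.14) was lost in 13 and MAGEA12 (-7.01 to -4.16) in 15 of 27 settings, and AFF3, NRG4 (1.67 to 1.93), PSMD5 (-9.35 to -7.08) and VRK1 (-1.10 to -0.56) in DN/DN against LoF/LoF each in 14 of 24. LINC01036 (-7.57 to -4.76 against wild type) was lost in 5 of 23 settings against wild type, 2 of 24 against LoF/LoF and 7 of 21 against DN/DN. Of the values of the named genes, apart from AFF3 against wild type and its paralogs, 372 under the planned settings and 175 under the added ones kept their direction and side of the threshold, 62 and 36 lost a call, 56 and 0 gained one, and 0 turned direction. For AFF1, AFF2 and AFF4, 321 and 130 values stayed within 1 SD between lines and 6 and 11 moved further, while 17 and 14 had the opposite sign and 6 and 0 passed the threshold. RLE size factors moved no median by more than 0.007. Leave-out runs hold fewer lines, and the cause of the other changes was not tested. A DESeq2 test of counts was not run, nor was the correlation over called genes only, which are too few. Reads limit genes near the floor, such as MAGEA12, PSMD5 and LINC01036, whose fitted folds depend on the prior count.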

Other observations

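The tests of hypotheses in this part were chosen after the results were seen. Other lists moved in DN/DN against wild type by camera with its preset correlation. Interferon response genes were higher (median 0.24, 23 of 29 above 0, adjusted p = 0.0112), with IFI6 at 1.35. So were neural progenitor transcription factors (0.21, 29 of 44, adjusted p = 0.0361), with the intermediate filament gene NES at 1.48, fibroblast markers (0.54, 9 of 12, adjusted p = 0.0399) and replication-dependent histones (0.43, 9 of 11, adjusted p = 0.0279). Cancer-testis antigens (10 of 16 below 0, adjusted p = 0.0386) and respiratory chain subunits (median -0.11, 52 of 72 below 0, adjusted p = 0.0447) were lower. With an estimated correlation the p values were 0.238, 0.222, 0.238, 0.551, 0.356 and 0.611. Adjusted over the list alone, COL1A1 (1.15), MMP2 (2.88) and COL3A1 (-3.48) of the fibroblast markers and MAGEA12 were called, and 0 over all genes. The interferon call was lost without line 54 (adjusted p = 0.216), and cancer-testis without 54 (0.126), 90 (0.125) or Wt4 (0.179). Fibroblast was lost without 54 (0.498), Wt2 (0.0666), letter A (0.0519) or C (0.0565) or library Wt4C (0.0507), and neural progenitor without 90 (0.419), Wt4 (0.067) or letter A (0.0691). Respiratory was lost without 90 (0.417), Wt4 (0.746), letter B (0.0632) or C (0.256) or library Wt4C (0.0817), and histones without 54 (0.0686), 90 (0.156), Wt2 (0.409) or letter C (0.113). With the log2 values as deposited the fibroblast (0.135), neural progenitor (0.0974), respiratory (0.174) and histone (0.0659) calls were lost, with the stricter filter the cancer-testis (0.0612) and respiratory (0.0675) calls, and with the local chromosomal median removed the fibroblast call (0.0579).

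In DN/DN against LoF/LoF, ATF4 targets (median 0.36, 31 of 36 above 0, adjusted p = 0.000772), extracellular matrix genes (0.32, 48 of 67, adjusted p = 0.00457), cartilage genes (0.09, 27 of 43, adjusted p = 0.0365) and metallothioneins (0.31, 5 of 5, adjusted p = 0.0385) were higher, and the metal-binding MT1F, at 1.94, was called when adjusted over the list alone. Immediate early genes (-0.40, 20 of 31 below 0, adjusted p = 0.0115), G2 and M phase genes (-0.13, 41 of 56, adjusted p = 0.0137) and p53 targets (-0.29, 23 of 28, adjusted p = 0.0137) were lower. With an estimated correlation the p values were 0.531, 0.194, 0.4, 0.387, 0.468, 0.531 and 0.531. All 7 were lost without line 54 (ATF4 0.494, matrix 0.164, cartilage 0.0744, metallothioneins 0.0808, immediate early 0.13, G2 and M 0.877, p53 0.0877), and ATF4 targets and G2 and M genes turned direction there. Without line 15 immediate early (0.0651), metallothionein (0.0651) and p53 (0.0526) calls were lost, without line 216 metallothionein (0.066) and p53 (0.131), without line 90 cartilage (0.215), metallothionein (0.215) and p53 (0.101), without line 98 G2 and M (0.116) and cartilage (0.0539), without line 20 cartilage (0.128) and without letter C metallothioneins (0.0622). The cartilage call was also lost with the log2 values as deposited (0.0688), the metallothionein call with the local chromosomal median removed (0.0695), and the immediate early and metallothionein calls with lines 4 and 15 left out (0.132 each). In DN/LoF against DN/DN fibroblast markers were lower (-0.77, 10 of 12, adjusted p = 0.0485, and 0.409 as the p with an estimated correlation), a call lost without 54 (0.543), 51 (0.0796) or 86 (0.115), letter B (0.0592) or C (0.0975). It was also lost with RLE size factors (0.0513), no low-count filter (0.0514), the stricter filter (0.122), the log2 values as deposited (0.0983) and lines 4 and 15 left out (0.0521). Of the 33 lists, 10 were called in no comparison. Their smallest adjusted p over the 7 comparisons was 0.0701 for the super elongation complex and AFF family and for mitochondrially encoded genes, 0.0833 for kidney development, 0.0987 for TGF-beta and BMP targets, 0.106 for canonical Wnt targets and for imprinted genes, 0.126 for hypoxia and glycolysis, 0.152 for hepatic and epithelial carcinoma markers, 0.441 for clustered protocadherins and 0.636 for hedgehog targets.

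NREP, called lower in LoF/LoF against wild type, and NRG4, lower there without a call (-1.39 ± 0.24, adjusted p = 0.152), may follow the level of AFF3. Over the 8 lines that are not LoF/LoF, the log2 level of NRG4 had Pearson r = 0.63 with AFF3 (exact permutation p = 0.09, adjusted 0.18) and Spearman rho = 0.67 (p = 0.083, adjusted 0.083), and r was 0.44 without lines 86 and Wt1. NREP had r = 0.49 (exact permutation p = 0.21, adjusted 0.21) and rho = 0.74 (p = 0.046, adjusted 0.083), and r was 0.53 without these lines. These are 2 relations in 1 family, and 8 lines are too few to decide either. The chromosomal neighbours of NRG4 also shifted, with medians of 0.21 and 0.10 in lines 54 and 90. They lay at -0.22, -0.19 and -0.21 in lines 51, 86 and 1, and at 0 to 0.02 in wild type. Those of NREP lay at -0.45 in line 90, where NREP was at 4.43 log2 CPM. The relations were not tested with the local median removed. AFF3 separates the LoF/LoF lines from the rest, so no r over all lines is given.

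Genes near 0 in some lines and expressed in others, under 0.1 CPM in at least 1 line and at 1 CPM or more in at least 2, numbered 319. Zinc finger genes, a large family of DNA-binding repressors that lie in clusters, may be over-represented among them: 21 of 521 zinc finger genes (4%) were of this kind against 2.2% of other genes, an odds ratio of 1.91 (Fisher's exact test, p = 0.009). Which genes count as zinc finger genes was set by their symbols after the values were seen, and neighbouring genes of a cluster are not independent.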
